A study of Mus musculus with 8 samples.

How the data were processed

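The samples were 8 sequencing libraries of 4-thiouridine (4sU) labelled RNA from mouse embryonic stem cells with conditional alleles of Ythdc1. They form 4 groups of 2 libraries: DMSO or 4-hydroxytamoxifen (4OHT), each with a label of 0 or 8 min. Groups were taken from the sample labels, and a column of the table whose name does not mention 4OHT was taken as DMSO. The sample titles give 1 embryonic stem cell number at 0 min and the other at 8 min, whereas the table's columns carry both numbers at both times. Columns were therefore assigned to groups only, and the main fit did not read the numbers 1 and 2 as lines or as pairs. Some later checks did compare libraries of the same number. Labelling time and cell line may change together. A 4 min label is mentioned in the protocol but has no library here.

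The authors deposited a single table of signal values with 38971 entries: 37795 genes, 1038 repeat types, 78 structural RNA types and 60 spike-in RNAs. Per the submitters' processing notes, bcl2fastq, STAR 2.7, Bowtie2 and the mm10 build were used, without the role of each. The deposited signal was in each library a whole number of reads divided by 1 number per library, between 8.1 and 29.5. Multiplied back, 99.978% to 100% of the entries came within 0.01 of a whole number. What the divisor stands for, the handling of reads that map to several places and the strand counted are not stated, so values of near-identical copies (Zscan4, histones, repeats) are uncertain. Names of 27329 entries matched a symbol of the annotation, from which coordinates (GRCm38.p6, mm10), biotypes and gene lengths were taken.

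The recovered reads (M, mega) numbered 61.4 M and 46.3 M with DMSO and 58.3 M and 57.6 M with 4OHT at 0 min. At 8 min they numbered 112 M and 93.1 M with DMSO and 118 M and 134 M with 4OHT. The transcript Gm26917 took 23.2% to 27.7% of reads at 0 min and 2.67% to 3.92% at 8 min. Reads are not independent molecules, so counting error understates the spread.

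Values were analysed as log2(value + 1) for entries of at least 10 in at least 2 of the 8 libraries, which left 20658 genes and 949 repeat types. Group means were fitted to all 8 libraries with limma 3.58.1 in R 4.3.3 (trended empirical Bayes, two-sided), and p-values were adjusted by Benjamini-Hochberg at 0.05 over genes, repeats and structural RNAs separately. The comparisons were 4OHT against DMSO at 0 min, at 8 min and as the mean of both times, the difference of the 8 and 0 min effects, and 8 against 0 min within DMSO and within 4OHT. A relative log2 fold change is the fitted value less the median of all genes. Adjusted p-values come from fits across all genes.

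Named genes were chosen by a rule. For 0 min, 8 min and the mean of both times, it took in each direction the 8 genes of largest change past the threshold whose 4OHT libraries all lay on the same side of the DMSO libraries, and filled empty places by smallest p. For the difference, the labelling-time comparisons and repeats it took 5 each way. From each gene list it took up to 3 members of smallest p, and Ythdc1 always. Genes shown outside the rule were chosen after their values were seen.

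In all, 24 gene lists were fixed: 2-cell-like genes, naive pluripotency, formative and neuroectoderm, mesoderm and primitive streak, primitive endoderm, trophoblast, fibroblast and feeder cells, m6A proteins, SR and 3-prime end proteins, retrotransposon silencing, germline, p53 targets, integrated stress response, immediate early, interferon-stimulated, Pol II elongation, long noncoding RNAs, histones, small nucleolar and Pol III RNAs, ribosomal proteins, mitochondrially encoded genes, and the MERVL, IAP and L1Md repeats. They were compared with all other entries by limma camera with a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Lists with fewer than 5 members measured were not tested. Protein-coding genes (13951) were grouped by length at 10, 30 and 100 kb. All of these choices were made before the data were examined.

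Chosen after the data were seen were 5 added lists (sterol genes, the same without the members seen first, fatty acid synthesis, glycolysis, endoplasmic reticulum stress), fits of only the 4 libraries of a comparison after median-ratio scaling or with edgeR or DESeq2, and scaling by spike-in reads. The 5 added lists were adjusted apart from the fixed lists. The fit of the 4 libraries of 8 min after median-ratio scaling is called the scaled 8 min fit. Its estimates equal the 8 min estimates of the fit with all 8 libraries scaled, and only the estimated spread differs. Alternatives fixed earlier were pseudocounts of 0.5 and 5, no filter, a minimum of 100, median-ratio scaling, quantile normalization, no trend, robust empirical Bayes, the 4 libraries of a comparison alone, a block for the library number, leaving out each library, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads.

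The 8 min comparison was tested on simulated data, with changes planted in 50 genes for each fold. The fit of all 8 libraries recovered 1 of 50 genes raised 2-fold, 30 of 50 raised 4-fold, 1 of 50 lowered to a fold of 0.5 and 17 of 50 lowered to a fold of 0.25, with 5 false calls. The scaled 8 min fit recovered 0, 17, 0 and 5 of 50, with 3 false calls. The simulated spread came from all 8 libraries, and the simulated values held no shift of the median gene. In the real data the 2 libraries of a group lay closer at 8 min (chi-square per degree of freedom 12.8 and 12.0) than at 0 min (44.3 and 55.1). These counts therefore do not give the recovery of either fit on the real values. Spike-in RNAs were used only for scaling, and no column of the table was left out.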

Results

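Newly made RNA was measured by 4sUDRB-seq in mouse embryonic stem cells with conditional alleles of Ythdc1, which encodes a nuclear reader of N6-methyladenosine (m6A). Cells were kept with 4-hydroxytamoxifen (4OHT, 1 μg/ml), the compound that starts deletion in inducible knockout lines, or with its solvent DMSO during 4 days. DRB at 100 μM, which stops RNA polymerase II (Pol II) near promoters, was then given during 3 h and washed away, and RNA was tagged with 1 mM 4sU during 0 or 8 min and purified. A label of 0 min leaves no labelling time, so the 0 min libraries may hold mainly RNA carried over without label. Values at 0 min, means of both times and changes with time therefore may not describe newly made RNA. Each of the 4 groups held 2 libraries, with 46.3 M to 61.4 M reads (M, mega) at 0 min and 93.1 M to 134 M at 8 min. The titles place 1 cell line number at 0 min and the other at 8 min while the table's columns carry both numbers at both times, so labelling time and line may differ together. With 2 libraries per group and nothing said about separate cultures, p-values measure only the spread between these samples, which may be technical. On the deposited scale, the median log2 fold change of all genes with 4OHT was 1.43 at 8 min, 0.28 at 0 min, 0.86 for the mean of both times and 1.15 for their difference. Changes are therefore also given relative to that median.

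Ythdc1, the targeted gene (gene ID 231386; GRCm38.p6 chromosome 5, 86803980 to 86836659), was read in every library. Its normalised read counts at 0 min were 133 and 185 with DMSO and 129 and 412 with 4OHT. At 8 min they were 1409 and 2708 with DMSO and 2696 and 5168 with 4OHT. The log2 fold change was 0.93 at 8 min (adjusted p = 0.174; relative −0.50), 0.55 at 0 min (adjusted p = 1), 0.74 for the mean of both (adjusted p = 0.156) and 0.38 for the difference (adjusted p = 0.735), none past the threshold. In the scaled 8 min fit, chosen after the data were seen, Ythdc1 fell by 0.62 on the log2 scale (adjusted p = 0.000255), from 1726 ± 258 to 1126 ± 161 (SD, n = 2), but it did not pass with all 8 libraries scaled (adjusted p = 0.47). Without 4OHT 0 min number 1, the mean effect was 1.16 (adjusted p = 0.0272), the 0 min effect 1.38 and the difference −0.45, and without number 2 they were 0.33, −0.28 and 1.22. The 8 min effect was 0.46 without DMSO 8 min number 1 and 1.41 without number 2. Which part of the gene is deleted is not stated, so reads over the whole gene measure the deletion poorly.

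At 8 min after release, several genes that mark the 2-cell embryo were among those of largest rise with 4OHT. Zscan4d (chromosome 7, 11161643 to 11166148), a 2-cell embryo marker linked to telomere upkeep, rose from a normalised read count of 4.47 ± 1.43 (SD, n = 2) to 147 ± 52.5, a log2 fold change of 4.74 ± 0.64 (SE; adjusted p = 1.14e-09; relative 3.30). Its near-identical copies Zscan4e (4.76), Zscan4b (4.48) and Zscan4-ps3 (4.59), and Gm5662 (4.55), rose alike, though reads shared between such copies leave each value uncertain. Slc5a12 (chromosome 2, 110597299 to 110649345), a sodium-coupled lactate transporter, rose from 5.14 ± 1.81 to 178 ± 120 (log2 fold change 4.72 ± 0.63; adjusted p = 1.14e-09; relative 3.28). The other genes of largest rise were the predicted genes Gm38258 (4.49) and 4931429L15Rik (4.45).

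Few genes fell on the deposited scale at 8 min. Ndp (chromosome X, 16885521 to 16911774), which encodes the Wnt-pathway ligand norrin, went from 6.44 ± 1.67 to 0.212 ± 0.0496 (SD, n = 2; log2 fold change −2.60 ± 0.65; adjusted p = 0.00174). Gpr3, a receptor that raises cyclic AMP (−2.44), Slc22a16, a carnitine transporter (−2.32), Kcnj1, a potassium channel (−2.26), Il23r, the interleukin 23 receptor (−2.16), the olfactory receptor Olfr698 (−2.08), and the unnamed AC154816.1 (−2.64) and Gm44127 (−2.53) were the other genes of largest fall. All but AC154816.1 lost the call when 1 library was left out. Without 4OHT 8 min number 2 the adjusted p was 0.0738 for Ndp, 0.127 for Gpr3, 0.128 for Slc22a16, 0.212 for Kcnj1 and 0.178 for Il23r. It was 0.146 for Olfr698 and 0.0873 for Gm44127 without 4OHT number 1, from 0.0562 to 0.0751 for all these but Ndp without DMSO number 1, and from 0.0715 to 0.0876 for Kcnj1, Il23r and Olfr698 without DMSO number 2.

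In all, 11723 of 20658 genes were higher and 26 lower with 4OHT at 8 min on the deposited scale. Relative to the other genes the scaled 8 min fit, chosen after the data were seen, called 3095 genes higher and 4494 lower, and on the same 4 libraries edgeR called 3746 and 3363 and DESeq2 3819 and 3390. The median gene lay at −0.078 in the scaled 8 min fit, which favours calls of lower genes. With the scaling fixed earlier, median-ratio scaling of all 8 libraries, limma called 2 higher, Stc2 (2.71) and the neutral amino acid transporter Slc1a4 (1.82), and 21 lower. Those 21 included the fatty acid desaturases Scd1 (−3.52) and Scd2 (−2.45) and the early growth response factor Egr1 (−1.98). The deposited-scale counts were 260 and 3 without DMSO number 1, 8272 and 5 without DMSO number 2, 10381 and 11 without 4OHT number 1, and 189 and 4 without 4OHT number 2. Of the members of the fixed gene lists, that 8-library scaling called 1 higher in the integrated stress response, 1 lower among immediate early genes and 0 in every other list.

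**Figure D1:**
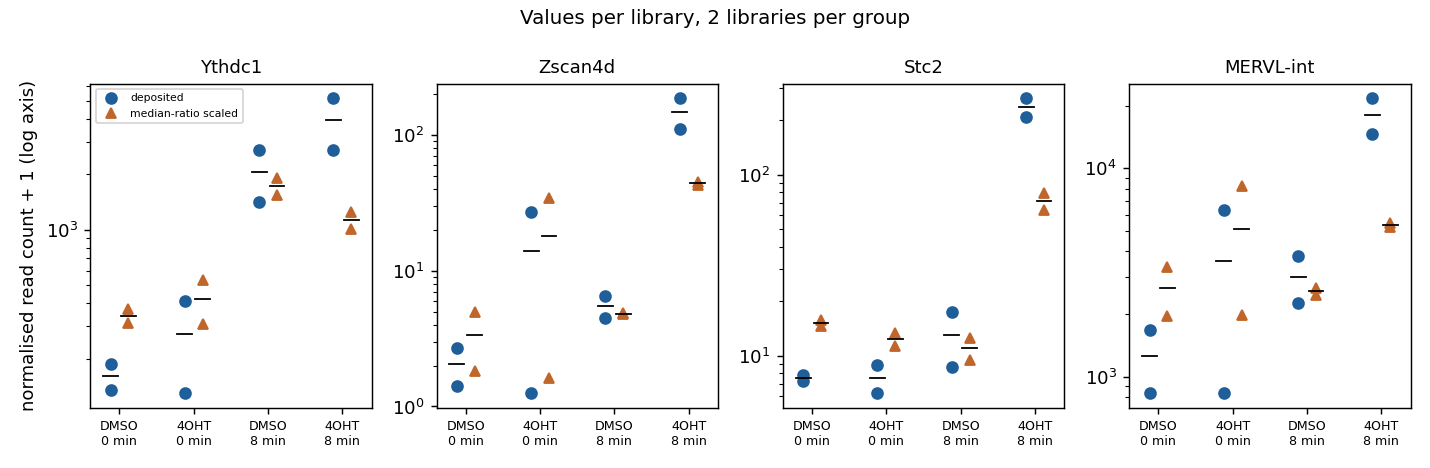
Normalised read count plus 1 (log axis) of Ythdc1, Zscan4d, Stc2 and the MERVL-int repeat in each of the 8 libraries, with circles for the deposited values, triangles for values after median-ratio scaling and bars for group means. Zscan4d read 110 and 184 in the 4OHT libraries of 8 min against 3.46 and 5.48 with DMSO, and at 0 min 4OHT number 2 read 25.8 against 0.256 in number 1.

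Of the 2-cell-like list at 8 min, 19 of 20 measured members were higher on the deposited scale, 19 adjusted over the list alone, with a median relative change of 2.39 (camera adjusted p = 1.66e-34; adjusted p = 0.281 with an estimated correlation). In the scaled 8 min fit 16 rose, including Zscan4d (3.18), Zscan4c (2.75) and Gm4340 (2.50), 0 fell and 4 did not pass, whereas with all 8 libraries scaled 0 members passed (Zscan4d 3.18; adjusted p = 0.357). The list as a whole still passed in that 8-library fit by camera with the preset correlation (adjusted p = 1.48e-14). An estimated correlation was not tried there. MERVL, the endogenous retrovirus whose long terminal repeat drives many 2-cell genes, had its internal part, MERVL-int, at 3023 ± 1096 with DMSO and 18130 ± 5049 with 4OHT (SD, n = 2; log2 fold change 2.60; adjusted p = 0.0529). In the scaled 8 min fit it rose from 2570 ± 150 to 5336 ± 183 (1.05 ± 0.11; adjusted p = 2.13e-07), and its promoter repeat MT2_Mm rose by 0.36 (adjusted p = 0.0203), but with all 8 libraries scaled neither passed (adjusted p = 0.999 for both). The 8 MERVL and MT2 types as a list had a median relative change of 0.02 (adjusted p = 0.929), with 0 members past the threshold over all repeats and 2 adjusted over the list alone.

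Genes of the integrated stress response, which adapts cells to amino acid shortage and misfolded protein, were higher as a group at 8 min. Of 22 members 16 were higher, and 19 adjusted over the list alone, with a median relative change of 0.40 (adjusted p = 0.000692; adjusted p = 0.975 with an estimated correlation). In the scaled 8 min fit 11 rose, 3 fell and 8 did not pass, against 1 higher and 0 lower with all 8 libraries scaled. With all 8 scaled, the list passed by camera with the preset correlation (adjusted p = 0.00514). Stc2, a secreted glycoprotein of the stress response, rose in the scaled 8 min fit from 9.95 ± 2.19 to 70.4 ± 10.3 (SD, n = 2; 2.71 ± 0.19; adjusted p = 3.03e-10). Chac1, which degrades glutathione (2.69), Trib3, an ATF4-induced pseudokinase (1.15), and Ddit3, the stress factor CHOP (0.82), rose as well. Targets of the tumour suppressor p53 were also higher, with 27 of 30 members passing, 28 adjusted over the list alone, and a median relative change of 0.19 (adjusted p = 0.0491; adjusted p = 0.975 with an estimated correlation). The cell-death gene Perp (1.77) and the death receptor Fas (1.19) were among the 7 that rose in the scaled 8 min fit, where 0 fell. Leaving out a 0 min library changes the shared estimate of spread but not the fold changes at 8 min. The p53 call was lost without DMSO 0 min number 1 (adjusted p = 0.12) or number 2 (0.107), DMSO 8 min number 1 (0.162), or 4OHT 8 min number 1 (0.0907) or number 2 (0.0526). On the deposited scale Fas (2.72) was lost without DMSO 8 min number 1 (0.141) or 4OHT 8 min number 2 (0.109).

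Replication-dependent histones lay low relative to other genes at 8 min, with a median relative change of −0.72 (adjusted p = 2.67e-13; adjusted p = 0.975 with an estimated correlation). With all 8 libraries scaled 0 of 70 members passed, while the list passed by camera with the preset correlation (adjusted p = 1.36e-16). On the deposited scale 1 member, Hist1h2be (1.77), was higher and 0 adjusted over the list alone, whereas in the scaled 8 min fit 69 fell, 0 rose and 1 did not pass. Hist1h1e (−0.35) and Hist2h4 (−0.36) were 2 of these, with deposited values of 1.20 and 1.17 that did not pass. Small nucleolar, spliceosomal and Pol III RNAs had a median relative change of −0.26 (adjusted p = 8.27e-05; adjusted p = 0.975 with an estimated correlation). Of 118 members 37 were higher on the deposited scale and 0 adjusted over the list alone, and in the scaled 8 min fit 36 fell. The structural entries for U3 (−1.53; adjusted p = 0.0151) and U8 (−2.01; adjusted p = 0.00859), small nucleolar RNAs that guide ribosomal RNA cleavage, fell after median-ratio scaling of all 8 libraries. A ribosomal RNA entry, LSU-rRNA_Hsa, fell as well (−1.55; adjusted p = 0.0361), so this fall was not particular to small nucleolar RNAs.

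Trophoblast markers had a median relative change of −0.76 (adjusted p = 0.00293; adjusted p = 0.975 with an estimated correlation). Of 13 members 2 were higher, 2 adjusted over the list alone. In the scaled 8 min fit 7 fell, among them the keratins Krt19 (−1.68) and Krt18 (−1.17), and Krt7 (1.18) rose. Fibroblast and feeder markers, which stem cells also express in part, had a median of −0.64 (adjusted p = 0.00855; adjusted p = 0.975 with an estimated correlation; 0.0551 without 4OHT 8 min number 1). Of 11 members 2 were higher, 1 adjusted over the list alone, and in the scaled 8 min fit 5 fell, including fibronectin, Fn1 (−0.62), and vimentin, Vim (−0.73).

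The other lists did not differ from the remaining genes at 8 min by camera on the deposited scale. Each count below gives members higher on the deposited scale, members adjusted over the list alone, and then those higher and lower in the scaled 8 min fit. Of 30 naive pluripotency genes, 16 passed, 16 over the list alone, 5 rose, including the transcription factor Gbx2 (1.4), and 9 fell, including Nanog (−1.08), a core pluripotency factor (adjusted p = 0.704 for the list). Formative and neuroectoderm genes counted 8 and 11 of 11, then 1 and 1 (adjusted p = 0.363). Mesoderm and primitive streak genes counted 6 and 6 of 10, then 2 and 3 (adjusted p = 0.671). Primitive endoderm genes counted 10 and 10 of 12, then 2 and 1 (adjusted p = 0.117; 0.0257 with all 8 libraries median-ratio scaled and 0.0646 in the scaled 8 min fit, where adjusted p = 0.416 with an estimated correlation), and the basement membrane laminins Lamb1 (1.51) and Lama1 (0.94) were those that rose. Germline genes counted 12 and 11 of 24, then 4 and 5 (adjusted p = 0.858). Immediate early genes counted 19 and 20 of 32, then 9, including the growth arrest gene Gadd45g (2.05), and 7, including Egr1 (−1.98) and Fos (−1.41; adjusted p = 0.764 for the list). Interferon-stimulated genes counted 13 and 14 of 18, then 5 and 2 (adjusted p = 0.477).

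For lists of RNA-processing and gene-control proteins, the counts are given in the same order, and over all genes the same fit called 3095 higher and 4494 lower, a balance that turned with edgeR and DESeq2. The m6A writers, erasers and readers counted 10 and 5 of 24, then 0 higher and 8 lower (adjusted p = 0.53; 0.0461 in the scaled 8 min fit, where adjusted p = 0.604 with an estimated correlation). SR, 3-prime end processing and export proteins counted 10 and 0 of 28, then 0 and 13 (adjusted p = 0.372; 0.00389 in the scaled 8 min fit, where adjusted p = 0.604 with an estimated correlation). Cytoplasmic ribosomal proteins counted 23 and 1 of 88, then 1 and 48 (adjusted p = 0.117; 1.4e-06 in the scaled 8 min fit, where adjusted p = 0.272 with an estimated correlation; 0.019 and 0.0237 on the deposited scale without DMSO 0 min number 1 or 2). Retrotransposon silencing genes counted 17 and 15 of 32, then 2 and 11 (adjusted p = 0.858). Pol II pausing and elongation genes counted 21 and 26 of 32, then 1 and 5 (adjusted p = 0.858). Long noncoding RNAs counted 15 and 15 of 22, then 4 and 4 (adjusted p = 0.348), where Mirg (1.26) and Meg3 (0.76) of the imprinted Dlk1-Dio3 region rose. No mitochondrially encoded gene was in the table under the list's prefix (0 members).

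Among repeats at 8 min, limma called 0 higher and 0 lower on the deposited scale, with 699 and 0 at an unadjusted p under 0.05. RLTR13A (2.09), RLTR31A_Mm (2.06), L1M2a (2.02), MER97b (2.09) and MERVL-int had the smallest p (adjusted p = 0.0529; 0.0267 to 0.0272 without 4OHT 0 min number 1 or 2). The scaled 8 min fit called 10 of 949 types higher and 87 lower, with the median type at −0.119, and median-ratio scaling of all 8 libraries called 0 and 0. The IAP and ETn list of endogenous retroviruses counted 0 over all repeats and 9 of 43 over the list alone, then 2 higher, MMETn-int (0.60) and ETnERV-int (0.59), and 14 lower (adjusted p = 0.117; 0.0353 in the scaled 8 min fit, where adjusted p = 0.416 with an estimated correlation). It also took names that start with MusD, RLTR10 or MMERVK10, such as RLTR10E, so not every member is named IAP or ETn. The L1Md list counted 0 and 6 of 12, then 0 higher and 5 lower, among them L1Md_A (−0.85) and L1Md_T (−0.66; adjusted p = 0.227 for the list). Its names were matched without regard to case, so L1MD1, L1MD3 and L1MDa were members too. The counts therefore do not describe young LINE-1 elements alone.

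**Figure D2:**
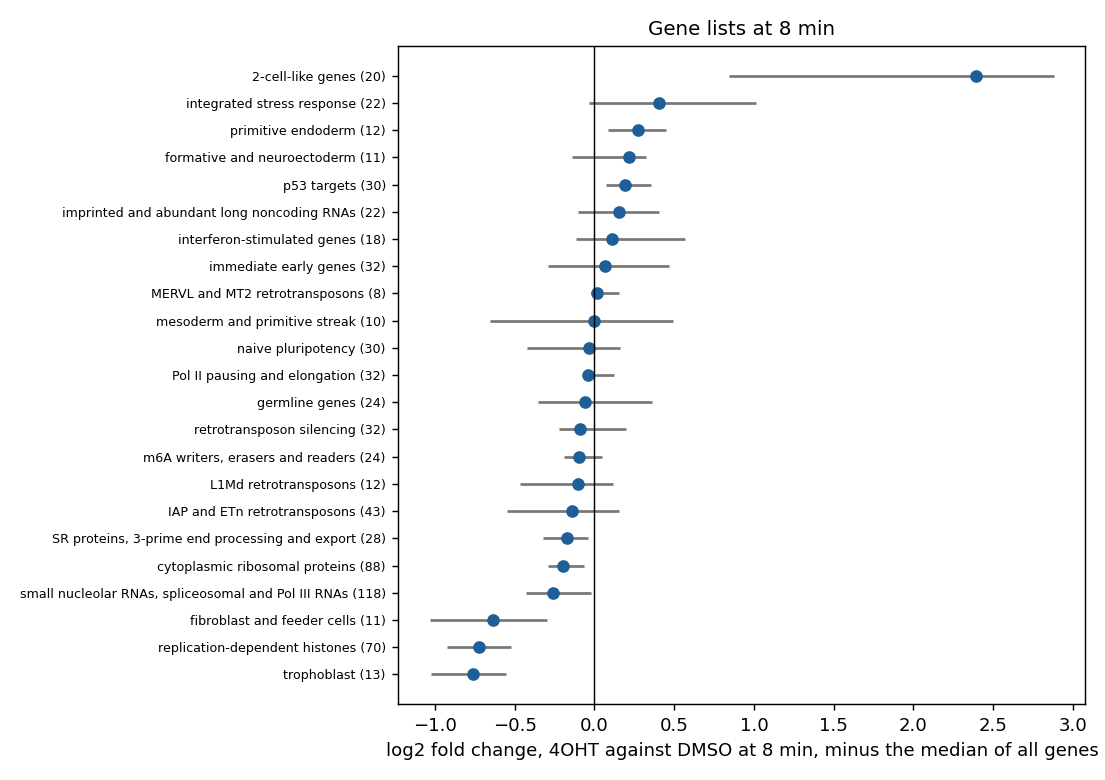
Log2 fold change of 4OHT over DMSO at 8 min less the median of all genes (horizontal axis), for each of 23 lists with its number of measured members, where dots are medians and lines run between quartiles. The 2-cell-like list had its median at 2.39 and the histones at −0.72.

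At 0 min, with no labelling time, 2-cell-like genes were also the list farthest above other genes, with a median relative change of 0.93 (adjusted p = 5.19e-09; adjusted p = 0.982 with an estimated correlation). The difference lay in 4OHT number 2: the list's median was 2.06 for this library less DMSO number 2 and 0.11 for 4OHT number 1 less DMSO number 1, and without 4OHT number 2 the list's adjusted p was 0.769. Zscan4-ps3 had the smallest p (log2 fold change 2.56 ± 0.65; adjusted p = 0.836), then Gm1401 (2.4), Gm38342 (2.37), the mucin Muc15 (2.4), Pla2g4a, a phospholipase that frees arachidonic acid (2.33), Gm45148 (2.34), the coactivator Ppargc1b (2.31) and Gm5142 (2.23). On the low side were the zinc finger genes Zfp189 (−1.82) and Zfp273 (−1.70), the cytochrome P450 Cyp2j9 (−1.79), the molybdenum cofactor gene Mocs1 (−1.69), S100a13 (−1.60), 1810013D15Rik, Gm26513 and Gm26830 (adjusted p = 1). None of these genes passed.

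By limma 0 genes were higher and 0 lower at 0 min, with 483 and 54 at an unadjusted p under 0.05. edgeR called 0 and 0, and DESeq2 89 and 36 with all 8 libraries and 0 and 0 with the 4 of 0 min. Without 4OHT number 1, limma called 191 higher and 2 lower, among them Zscan4-ps3 (3.99; adjusted p = 0.000151), Muc15 (3.65) and Pla2g4a (3.25). Histones had a median relative change of −0.18 (adjusted p = 0.0097) and small nucleolar and Pol III RNAs −0.18 (adjusted p = 0.000432), both with adjusted p = 0.982 with an estimated correlation. Without DMSO number 1 the histones turned to the other direction (adjusted p = 0.775) and the small RNAs gave 0.345, and without 4OHT number 2 the histones turned with 0.000582 and the small RNAs gave 0.769. The other 20 lists tested had adjusted p from 0.22 to 0.94, and no list had a member past the threshold, adjusted over all entries or adjusted over the list alone (0 of each). The IAP and ETn list (adjusted p = 0.94) passed without DMSO number 1 (0.0354), DMSO number 2 (0.0396, the other direction) or 4OHT number 2 (0.0441). Of the repeats 0 passed by limma (4 and 0 at an unadjusted p under 0.05). MER127 (2.05) and RLTR5_Mm (1.36) were highest by p and Charlie10b (−1.12) and MER92C (−1.07) lowest (adjusted p = 0.92), and MER127 passed without 4OHT number 1 (3.20; adjusted p = 0.00794).

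Averaged over both times, 2-cell-like genes again stood highest: 17 of 20 were higher, 19 adjusted over the list alone, with a median relative change of 1.62 (adjusted p = 1.8e-36; adjusted p = 0.255 with an estimated correlation). Zscan4-ps3 rose by 3.58 ± 0.46 (SE; adjusted p = 1.5e-10; relative 2.72). Herpud1 (chromosome 8, 94386429 to 94395371), a membrane protein made under endoplasmic reticulum stress, rose by 2.81 (adjusted p = 1.76e-07; relative 1.95), from 2.26 ± 0.83 to 12.9 ± 13.3 at 0 min and from 55.3 ± 10.7 to 864 ± 130 at 8 min (SD, n = 2). Wt1 (chromosome 2, 105126529 to 105173614), a zinc finger transcription factor, rose by 2.78 (relative 1.93) and Muc15 by 2.74 (relative 1.88), with Gm12794 (3.04), Gm21293 (2.91), 4933400F21Rik (2.76) and Gm37954 (2.71). Nfkbie, an inhibitor of NF-kappa-B (−0.91; adjusted p = 0.0968), did not pass, except without 4OHT 0 min number 1 (−1.10; adjusted p = 0.0373). The 5 genes past the threshold as lower did not separate the libraries at both times: Ndp (−1.25), AC154816.1 (−1.29), Slc22a16 (−1.17), Gm44127 (−1.16) and Adipoq, the adipocyte hormone adiponectin (−1.13), were named after their values were seen.

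For this mean, 4711 genes were higher and 5 lower. After median-ratio scaling limma called 0 and 0 genes (10269 and 18 at an unadjusted p under 0.05 on the deposited scale). On the recovered reads, each with its own scaling, edgeR called 0 and 0 and DESeq2 251 and 241. The structural entries U3 (−0.94; adjusted p = 0.0378) and U8 (−1.23; adjusted p = 0.0236) were lower by limma after median-ratio scaling. The counts were 1150 and 1 without DMSO 0 min number 1, 1426 and 0 without number 2, 11341 and 11 without 4OHT 0 min number 1, and 407 and 3 without number 2. They were 220 and 0 without DMSO 8 min number 1, 2746 and 0 without number 2, 4052 and 0 without 4OHT 8 min number 1, and 231 and 0 without number 2. Besides the 2-cell-like genes, 5 lists passed, all with adjusted p = 0.956 with an estimated correlation. Histones had a median relative change of −0.46 (adjusted p = 7.14e-13; 0 of 70 higher, 0 adjusted over the list alone) and small nucleolar and Pol III RNAs −0.22 (adjusted p = 2.59e-07; 7 of 118, 0 adjusted over the list alone). Trophoblast markers had −0.43 (adjusted p = 0.0132; 2 of 13, 2 adjusted over the list alone; 0.0908 without DMSO 0 min number 1 and 0.0745 without 4OHT 0 min number 2). Targets of p53, including Perp (2.03), had 0.19 (adjusted p = 0.0149; 11 of 30, 27 adjusted over the list alone), lost without DMSO 0 min number 1 (0.11) or 2 (0.055) or 4OHT 0 min number 2 (0.104). The integrated stress response had 0.21 (adjusted p = 0.0198; 10 of 22, 15 adjusted over the list alone), lost without DMSO 0 min number 2 (0.313) or 4OHT 0 min number 1 (0.631). The other 17 lists tested had adjusted p from 0.0824 to 0.852. Of these, the fibroblast markers passed without DMSO 8 min number 1 (0.0402) or 4OHT 8 min number 2 (0.0311), the IAP and ETn types without DMSO 0 min number 1 (0.00322) or 4OHT 0 min number 2 (0.00538), and the ribosomal proteins without DMSO 0 min number 2 (0.0166). Of the repeats 0 passed by limma (409 and 0 at an unadjusted p under 0.05), and MER127 was highest by p (1.76; adjusted p = 0.0944; 0.00042 without 4OHT 0 min number 1). Without that library MamRep1527 (0.00138), MER110 (0.00936), SRV_MM-int (0.00876) and RLTR31_Mm (0.00768), the next by p, passed as well.

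The difference of effects asks whether 4OHT changed RNA more at 8 than at 0 min. Stc2 (chromosome 11, 31359441 to 31370061) was among the named genes that passed: it read 6.53 ± 0.355 with DMSO and 6.55 ± 1.91 with 4OHT at 0 min, and 12 ± 6.12 and 235 ± 39.7 at 8 min (SD, n = 2; difference 4.27 ± 0.89; adjusted p = 0.00709; relative 3.12). Fam26e (4.78; adjusted p = 0.00555), RMST_1, an entry for a conserved part of a long noncoding RNA (4.51), AC159474.1 (4.50) and AI504432 (4.20) also passed. On the low side Gpr3 (−2.98; adjusted p = 0.106), AC154816.1 (−2.70), Gm44127 (−2.73), Gm8298 (−2.67) and Kcnj1 (−2.63) did not pass. In all, 79 genes were higher and 0 lower (3447 and 22 at an unadjusted p under 0.05). With median-ratio scaling limma called 0 and 0, and on the recovered reads edgeR called 0 and 0 and DESeq2 37 and 113. The counts were 0 and 0 without DMSO 0 min number 2, 1653 and 0 without 4OHT 0 min number 2, 95 and 5 without 4OHT 0 min number 1, 0 and 0 without DMSO 8 min number 1 or 4OHT 8 min number 2, 1 and 0 without DMSO 8 min number 2, and 3 and 0 without 4OHT 8 min number 1. Stc2 was lost without DMSO 0 min number 2 (adjusted p = 0.16), DMSO 8 min number 1 (0.307) or 2 (0.0543), or 4OHT 8 min number 1 (0.0573) or 2 (0.258). The other 4 genes that passed were lost without DMSO 0 min number 2 (0.16 to 0.233), DMSO 8 min number 1 (0.0508 to 0.307) or 4OHT 8 min number 2 (0.0945 to 0.347), all but RMST_1 without DMSO 8 min number 2 (0.0615 to 0.106), and AI504432 also without 4OHT 0 min number 1 (0.115) or 4OHT 8 min number 1 (0.0573). Without 4OHT 0 min number 1, Gpr3 (0.0147), AC154816.1 (0.0419), Gm44127 (0.017) and Kcnj1 (0.0376) passed as lower. Of the repeats 0 passed by limma (29 and 0 at an unadjusted p under 0.05), with MER97d highest by p (2.79; adjusted p = 0.421).

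The named genes that gained most RNA between 0 and 8 min had varied roles. In DMSO, Plk2 (chromosome 13, 110395044 to 110400844), a polo-like kinase and p53 target, rose from 6.81 ± 4.45 to 1279 ± 407 (SD, n = 2; log2 fold change 7.45 ± 0.60; adjusted p = 4.17e-31), Rnf103, a ubiquitin ligase of the endoplasmic reticulum, by 7.09, and Ifrd1, a transcriptional coregulator, by 7.02, with AL590614.2 (7.22) and Gm37115 (6.89). Proz, a vitamin K-dependent plasma protein (−2.81), Spatc1l (−2.69), the overlapping transcript Gm15343 (−2.79), 6430562O15Rik (−2.84) and AC126459.2 (−2.75) fell. In 4OHT, Ifrd1 rose from 42.1 ± 25.1 to 10548 ± 3721 (8.02 ± 0.63; adjusted p = 1.43e-33), Sertad1, a cell-cycle regulator, by 7.90, the pyruvate dehydrogenase subunit gene Pdhx by 7.76, Eny2 of the SAGA complex by 7.70 and Gm38190 by 7.68. Kcnj1 (−3.96) and its neighbour on chromosome 9 Fli1, an ETS transcription factor (−3.57), the interferon gene Ifna13 (−3.77), AC154816.1 (−3.43) and Ndp (−3.25) fell. The difference of the labelling-time effects between DMSO and 4OHT is the difference of effects given above.

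The median gene rose by 1.25 with time in DMSO and by 2.49 in 4OHT. On the deposited scale 9614 genes were higher and 389 lower in DMSO, and 15251 and 167 in 4OHT. After median-ratio scaling, 6194 were higher and 5631 lower in DMSO, and 5999 and 5830 in 4OHT. The DMSO counts were 7676 and 51 without DMSO 0 min number 2, 8909 and 68 without DMSO 8 min number 1, and 5656 and 213 without number 2. The 4OHT counts were 12897 and 330 without 4OHT 0 min number 1, 16014 and 78 without number 2, and 15220 and 49 without 4OHT 8 min number 1. Of the repeats, 412 rose in DMSO and 895 in 4OHT, and 0 fell by limma on the deposited scale (2 and 0 lower at an unadjusted p under 0.05). After median-ratio scaling 30 rose and 25 fell in DMSO, and 14 and 29 in 4OHT. RLTR13A2 (4.52 in DMSO, 5.37 in 4OHT) and MER110-int (4.26 and 5.31) rose most, with the retrovirus MMERVK10C-int (3.48), L1Md_Gf (3.43) and RLTR50B (3.38) in DMSO, and Charlie11 (4.73), Charlie10b (4.66) and RLTR20B4_MM (4.45) in 4OHT. MMERVK10C-int was lost without DMSO 0 min number 1 (adjusted p = 0.143) or DMSO 8 min number 2 (0.115). MER50 (−1.4; adjusted p = 0.0627), which did not pass, passed without 4OHT 0 min number 1 (0.035) or 2 (0.0363), as did ORR1G-int (0.0381 and 0.0389) and FordPrefect (0.0303 and 0.0261).

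The change from 0 to 8 min, with which the cell line may change too, differed by gene length, highest for genes of 10 to 30 kb and lowest over 100 kb. Between libraries of a group, the class medians on the deposited scale had an SD of 0.35 under 10 kb to 0.57 over 100 kb. That SD includes shifts of whole libraries, which relative changes remove in part. In DMSO the median relative change was 0.26 for 2949 genes under 10 kb, 0.49 for 4551 genes of 10 to 30 kb (adjusted p = 0.00092), 0.10 for 4194 genes of 30 to 100 kb and −0.47 for 2257 genes over 100 kb (adjusted p = 0.00412; adjusted p = 0.932 with an estimated correlation for each class). In 4OHT the medians were 0.19, 0.49 (adjusted p = 0.000474), 0.19 and −0.46 (adjusted p = 0.011; adjusted p = 0.864 with an estimated correlation). The effect of 4OHT differed little by length: at 8 min the medians were −0.10, 0.03, 0.14 and 0.12, where genes of 30 to 100 kb passed (adjusted p = 0.0112; adjusted p = 0.892 with an estimated correlation), and at 0 min −0.05, 0.00, 0.05 and 0.07. For the mean of both times they were −0.08, 0.01, 0.10 (adjusted p = 0.0124) and 0.11 (adjusted p = 0.0147; adjusted p = 0.91 with an estimated correlation for each). Genes are not independent replicates, and the gene count does not show how far Pol II had moved along each gene.

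**Figure D3:**
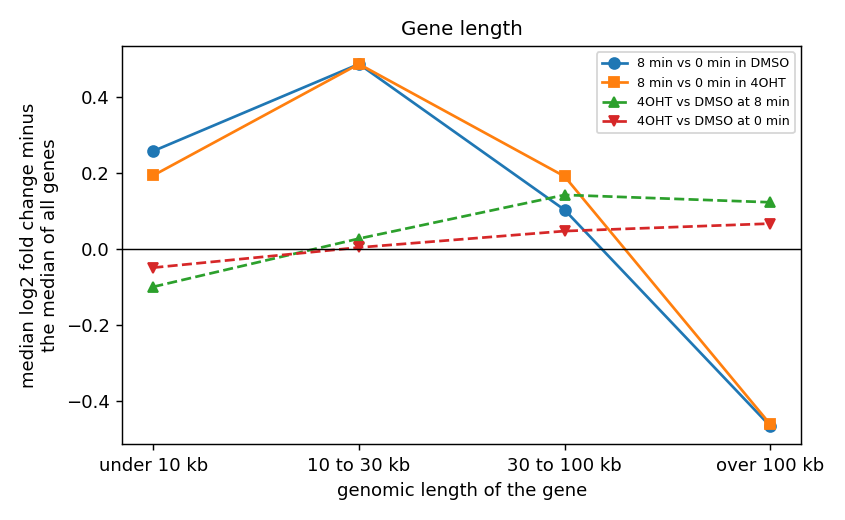
Median log2 fold change less the median of all genes (vertical axis) of protein-coding genes in 4 classes of gene length, under 10 kb to over 100 kb, for 4 comparisons shown as lines. The labelling-time lines fall to −0.47 in DMSO and −0.46 in 4OHT over 100 kb, and the 4OHT lines stay between −0.10 and 0.14.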

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

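The tests in this part were chosen after the results were seen, except the count of splits of the libraries, which was written down earlier. At 8 min most genes were higher with 4OHT on the deposited scale, and a scale factor per library or more labelled RNA per cell could each give that. The 204 entries that fell at least 4-fold from 0 to 8 min relative to the median gene, as RNA carried over without label would, had a median log2 change of 1.35 (quartiles 0.82 to 1.54), near the 1.43 of all genes, which is consistent with a scale factor. Per spike-in read, the median gene changed by 0.127 as a mean, with −0.61 within number 1 and 0.87 within number 2, so this test could not tell.

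The library labelled 4OHT number 1 at 0 min lay close to DMSO number 1 (chi-square per degree of freedom 13.9) but not to DMSO number 2 (43.2), and this was tested after the results were seen. Across 7589 genes its difference from DMSO number 1 had a correlation of 0.0178 with the 8 min effect, as if that effect may be missing from this library. A swap with DMSO number 2 would give DMSO number 2 less DMSO number 1 the 8 min effect, but that correlation was 0.0185, and the difference within number 2 kept a correlation of 0.319. Incomplete deletion or a different culture could each give the correlation of 0.0178, and these could not be told apart. The shared number could give the closeness to DMSO number 1, but what both libraries share cancels in their difference.

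The number of genes changed by 4OHT was compared with other splits of the 8 libraries, on the deposited scale. The model held only labelling time and the split, not the 4 group means, so its real count differs from the 4711 and 5 given above. On this scale a scale factor per library moves most genes together, so the counts may rank the splits by library scale. Of 34 splits, the real one included, 4 gave at least the real 706 genes, and the highest other gave 9801, so chance is not excluded and other structure among the samples may explain such a count. The split of 9801 genes placed 4OHT number 1 of 0 min with the DMSO libraries in place of DMSO number 2. A further split could not be fitted.

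The difference between the effects at 8 and 0 min passed the threshold as higher in 79 genes on the deposited scale and in 0 after median-ratio scaling by limma (3447 at an unadjusted p under 0.05 on the deposited scale; edgeR 0, DESeq2 37). Leaving out single libraries moved this count strongly both up and down, as given above. The named genes were Fam26e at 4.78, RMST_1 at 4.51, AC159474.1 at 4.50, Stc2 at 4.27 and AI504432 at 4.20. Spike-in reads made up at most 0.668% of a library and were used only for scaling.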

How the results depend on the processing

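The analysis was repeated under 25 settings, 21 fixed earlier and 4 added after the data were seen, and 8 of them leave out a library. Of 7084 values of 319 named genes, repeats and list members, 5774 were the same as in the deposited-scale fit, 1033 were weaker, 268 stronger and 9 reversed. A change of sign with neither value past the threshold was counted as the same. Of 1452 values of 108 other results, 1223 were the same, 32 weaker, 36 stronger, 149 moved and 12 reversed. In each pair of counts below, genes higher come before genes lower. The cause was not tested for any change, but 2 follow from the design. Median-ratio scaling removes most of the shift of the median gene, which stayed at −0.078 at 8 min. Leaving out a library of 1 time changes the 4OHT result at the other time only through the shared estimate of spread.

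Median-ratio scaling of all 8 libraries left 2 genes higher at 8 min, 0 and 0 for the mean of both times and 0 higher for the difference. With time it gave 6194 and 5631 in DMSO and 5999 and 5830 in 4OHT. Quantile normalization gave 18 and 52 at 8 min, 0 and 0 for the mean and 0 higher for the difference. With time it gave 5802 and 6046 in DMSO and 5993 and 5892 in 4OHT. Spike-in scaling, an added setting, gave 28 and 2 at 8 min, 10 and 0 for the mean and 1 higher for the difference, and 0 lower with time in DMSO and 6 lower in 4OHT.

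The edgeR fit called 2 genes higher at 8 min, 0 and 0 for the mean and 0 higher for the difference. With time it called 5569 and 5548 in DMSO and 5646 and 5563 in 4OHT. DESeq2 called 89 and 36 at 0 min, 275 and 497 at 8 min, 251 and 241 for the mean and 37 and 113 for the difference. With time DESeq2 called 6303 and 6036 in DMSO and 6159 and 6239 in 4OHT.

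Fitting only the 4 libraries of a comparison, with settings added after the data were seen, gave many genes in both directions at 8 min. After median-ratio scaling limma called 3095 and 4494 at 8 min, 6020 and 5508 with time in DMSO, and 5557 and 5374 in 4OHT. With edgeR the counts were 3746 and 3363 at 8 min, 5406 and 5395 with time in DMSO, and 5034 and 5237 in 4OHT. With DESeq2 they were 3819 and 3390 at 8 min, 5931 and 5830 with time in DMSO, and 5606 and 5899 in 4OHT.

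Without a filter there were 5794 and 47 genes at 8 min, 0 and 0 for the mean, 0 higher for the difference, 197 lower with time in DMSO and 259 lower in 4OHT. A minimum of 100 gave 7365 and 6 at 8 min, 3023 and 2 for the mean and 2 higher for the difference. With time that minimum gave 6228 and 123 in DMSO and 8739 and 32 in 4OHT. A pseudocount of 5 gave 7135 higher for the mean and 498 higher for the difference, and a pseudocount of 0.5 gave 23 higher for the difference. Without a trend 152 genes were higher for the difference.

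Whether the numbers pair libraries was checked, for the replicate block, by correlating deviations from group means between groups. The correlation was 0.415 between DMSO and 4OHT at 0 min, 0.140 between DMSO at both times, 0.147 between 4OHT at 0 min and DMSO at 8 min, and 0.0943, 0.0222 and 0.0189 for the other pairs of groups. At 0 min, libraries with the same number were also closer (chi-square per degree of freedom 13.9 and 29.4) than libraries of the same group (44.3 and 55.1), and the spike-in share was 0.120% and 0.101% in number 1 against 0.618% and 0.668% in number 2. This hints at a shared batch at 0 min, but the labels do not say so and not every pair of groups was over 0.1. With a replicate block for the library number, 66 genes were lower at 8 min, 14941 and 25 passed for the mean, and 6410 and 24 for the difference. The block gave 1142 lower with time in DMSO and 307 lower in 4OHT. Under the block Ythdc1 passed at 8 min (0.93; adjusted p = 0.0127) and for the mean (0.74; adjusted p = 0.00808). Lists gained with the block were p53 targets at 0 min (adjusted p = 0.0246), long noncoding RNAs at 8 min (0.00814) and for the mean (0.0236), and fibroblast markers (0.0262) and retrotransposon silencing genes (0.0236) for the mean. These used the preset correlation, and without the block the same lists had adjusted p = 0.982 at 0 min, 0.975 at 8 min and 0.956 for the mean with an estimated correlation.

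Ythdc1 at 8 min reversed in the added 4-library fits, to −0.62 with limma after median-ratio scaling (adjusted p = 0.000255), −0.53 with edgeR (0.00169) and −0.53 with DESeq2 (0.000145). Leaving out 4OHT 0 min number 2 or 1 moved its mean effect to 0.33 or 1.16, its 0 min effect to −0.28 or 1.38 and its difference to 1.22 or −0.45. Leaving out DMSO 8 min number 1 or 2 moved its 8 min effect to 0.46 or 1.41. Fibrillin, Fbn1, reversed at 8 min to −0.18 with median-ratio scaling of 8 or 4 libraries, −0.0614 with quantile normalization, −0.10 with edgeR on 8 or 4 libraries, −0.17 with DESeq2 and −0.10 with DESeq2 on 4. The histone genes Hist1h1e (−0.35) and Hist2h4 (−0.36) reversed in the 4-library median-ratio fit.

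With an estimated correlation on the deposited scale, 0 of the lists fixed earlier passed at 0 min, 0 at 8 min and 0 for the mean. Its adjusted p was 0.982 at 0 min for 2-cell-like genes, histones and small nucleolar and Pol III RNAs. At 8 min it was 0.281 for 2-cell-like genes and 0.975 for trophoblast markers, fibroblast markers, p53 targets, the integrated stress response, histones and small RNAs. For the mean it was 0.255 for 2-cell-like genes and 0.956 for trophoblast markers, p53 targets, the integrated stress response, histones and small RNAs.

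After median-ratio scaling of all 8 libraries 12 lists passed at 8 min. Gained were primitive endoderm (adjusted p = 0.0257; mean 0.0309), m6A proteins (0.0417), SR and 3-prime end proteins (0.00887; mean 0.0309), ribosomal proteins (3.11e-06; mean 1.71e-05) and IAP and ETn types (0.0417). In the added 4-library fit 11 passed, with m6A proteins (0.0461), SR and 3-prime end proteins (0.00389), ribosomal proteins (1.4e-06) and IAP and ETn types (0.0353) gained. With an estimated correlation in that fit, the gained lists had adjusted p = 0.604, 0.604, 0.272 and 0.416 in the same order. Quantile normalization gained primitive endoderm (0.0226; mean 0.0300), SR and 3-prime end proteins (0.0192; mean 0.0426), ribosomal proteins (5.66e-06; mean 3.22e-05) and fibroblast markers (mean 0.0426), and 10 lists passed for the mean.

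Length-class medians after median-ratio scaling, from short to long, were −0.18, −0.0624, 0.0489 and 0.0289 for 4OHT at 8 min and −0.11, −0.0359, 0.0386 and 0.0493 for the mean. With time they were 0.32, 0.53, 0.11 and −0.47 in DMSO and 0.29, 0.52, 0.21 and −0.46 in 4OHT. Leaving out 4OHT 0 min number 2 or 1 moved the deposited-scale medians at 0 min to −0.17 or 0.84 for 30 to 100 kb and to −0.29 or 1.00 over 100 kb. With time in 4OHT, leaving out number 1 or 2 moved them to 2.21 or 3.17 for 30 to 100 kb and to 1.4 or 2.64 over 100 kb.

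Leaving out each library in turn gave 0 to 191 genes higher and 0 to 2 lower at 0 min, both highest without 4OHT 0 min number 1. At 8 min it gave 189 higher without 4OHT 8 min number 2 to 14271 without 4OHT 0 min number 2, and 3 lower without DMSO 8 min number 1 to 36. For the mean it gave 220 higher without DMSO 8 min number 1 to 11341 without 4OHT 0 min number 1, and 0 to 11 lower. For the difference it gave 0 to 1653 higher, the latter without 4OHT 0 min number 2, and 0 to 5 lower. With time in DMSO it gave 5656 higher without DMSO 8 min number 2 to 10251, and 51 lower without DMSO 0 min number 2 to 542. With time in 4OHT it gave 49 lower without 4OHT 8 min number 1 to 330 without 4OHT 0 min number 1.

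The adjusted p of lists at 0 min ranged, over the libraries left out, from 6.86e-11 to 0.769 for 2-cell-like genes, 1.19e-10 to 0.775 for histones, 0.000124 to 0.769 for small RNAs and 0.0354 to 0.942 for IAP and ETn types. At 8 min it ranged from 0.00294 to 0.0551 for fibroblast markers, 0.0106 to 0.162 for p53 targets and 0.019 to 0.179 for ribosomal proteins. For the mean it ranged from 0.00700 to 0.0908 for trophoblast markers, 0.0311 to 0.333 for fibroblast markers and 0.00408 to 0.11 for p53 targets. It also ranged from 9.85e-05 to 0.631 for the integrated stress response, 0.0166 to 0.435 for ribosomal proteins and 0.00322 to 0.989 for IAP and ETn types.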

Other observations

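Genes that make and take up sterols were lower with 4OHT at 8 min relative to other genes, a list added after the data were seen. Its 25 members had a median relative change of −1.22 (adjusted p = 2.13e-17; adjusted p = 0.261 with an estimated correlation). In the scaled 8 min fit 24 fell, 25 adjusted over the list alone, 0 rose and 1 did not pass (adjusted p = 0.0487 with an estimated correlation). With median-ratio scaling of all 8 libraries 0 members passed, while the list passed by camera with the preset correlation (adjusted p = 1.49e-26). The epoxidase Sqle fell by 1.62 on the log2 scale and the isomerase Idi1 by 1.53. On the deposited scale 0 members passed as lower, so the direction holds relative to the median gene.

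Fatty acid and glycolysis genes lay low as well, in lists that have no version without the members seen first. Of 18 fatty acid genes 1 was higher and 1 lower on the deposited scale, while 14 fell in the scaled 8 min fit, 2 with all 8 libraries scaled, and 0 rose (median relative change −0.61 on the deposited scale; adjusted p = 5.82e-07; adjusted p = 0.346 with an estimated correlation, and 0.0487 in the scaled 8 min fit), with the desaturase Scd1 (−3.52) and the synthase Fasn (−1.20). Of 20 glycolysis genes 6 were higher and 0 lower on the deposited scale, while 11 fell and 1 rose in the scaled fit (−0.30 on the deposited scale; adjusted p = 0.000432; adjusted p = 0.463 with an estimated correlation, and 0.04999, just under the threshold, in the scaled 8 min fit), with the glucose transporter Slc2a3 (−1.37) and lactate dehydrogenase Ldha (−1.10). Of 21 endoplasmic reticulum stress genes 13 were higher and 0 lower on the deposited scale (0.19; adjusted p = 0.0657), while in the scaled fit 4 rose, Herpud1 by 2.4, and 6 fell. With all 8 libraries scaled, 0 members of the glycolysis or endoplasmic reticulum stress lists passed. By camera with the preset correlation in that fit, adjusted p was 2.53e-10 for fatty acid genes, 3.47e-05 for glycolysis and 0.219 for endoplasmic reticulum stress.

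Whether the rest of the sterol pathway fell was tested after the results were seen. The 19 members not seen first had a median relative change of −1.01 (adjusted p = 2.52e-12; adjusted p = 0.261 with an estimated correlation, and 0.0487 in the scaled 8 min fit), and 18 of them fell in the scaled 8 min fit, against 0 with all 8 libraries scaled. With all 8 scaled, the 19 as a list passed by camera with the preset correlation (adjusted p = 7.84e-19). Lower activity of the sterol-sensing transcription factors is a candidate explanation, and a different medium or density of the cultures could give the same change. The data hold no measure of sterol, so these could not be told apart.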
